A study of Arabidopsis halleri with 12 samples.

How the data were processed

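Root RNA of Arabidopsis halleri, a zinc hyperaccumulator, was profiled on 12 single-colour arrays carrying biotin-labelled RNA. Per the labels, 6 arrays came from the Langelsheim wild type (WT) and 6 from a line in which AhNAS2 was suppressed by RNA interference (RNAi). Each line was grown hydroponically for 5 weeks in a control Hoagland solution or in the same solution with 10 µM zinc added, which gave 4 groups of 3 arrays. Per the series' design text, each sample pooled the roots of 3 clonal plants and 3 independent experiments were done. No label ties a replicate number to an experiment, so p-values measure the spread between these pooled samples. Deviations of same-numbered arrays from their group means were correlated to see whether the numbers pair the samples. In control medium all 3 pairs of a WT and an RNAi array correlated above 0.1 (0.16 to 0.48). This is only a hint of pairing: 1 of 6 ways to match these arrays, the labelled one, had so high a mean, and 6 are too few to decide. In added zinc 1 of 3 pairs correlated above 0.1, and between the media 0 of 3 in WT and 2 of 3 in RNAi. Only 1 RNAi line was profiled, so effects of suppression and other differences between this line and WT cannot be told apart in any line comparison.

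The deposited values were log2 expression summaries per probe set, and per the submitters' processing notes RMA and the affy package were used. Tool versions, the background step, the quantile step and the probe definition file are not given in the sources used here. The values were used on the deposited log2 scale with no further scaling or filter. They ran from 2.46 to 14.3, the array medians lay between 5.34 and 5.38, and the correlation between arrays lay between 0.983 and 0.996. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.11 within a medium or line, 0.077 over both media or both lines, and 0.15 for the interaction. In each group replicates 1 and 2, the only pair compared, held the same values for at most 0.044% of probe sets.

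The table held 22810 probe sets, of which 64 control probe sets were left out of all tests, leaving 22746. The annotation table paired 13513 of these with exactly 1 gene and 503 with several genes, and 8730 were unlisted and stay unnamed. Together they covered 13350 different genes, and 152 genes had more than 1 probe set. Gene names are those of A. thaliana, so the signal of an A. halleri transcript also depends on how well it matches the probes.

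A group-means model was fitted over all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 3.79 prior degrees of freedom). The 7 comparisons were RNAi against WT in control medium, in added zinc and over both media, added zinc against control in WT, in RNAi and over both lines, and the interaction of line and zinc. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 22746 probe sets of each comparison, with a threshold of 0.05. Group means are given with SD and n = 3, and fold changes with the limma standard error (SE). Differences are RNAi minus WT or added zinc minus control throughout.

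Design, tests, gene lists and the rule for named genes were fixed before the data were examined. In the comparisons within a medium or line, the rule took the 10 highest and 10 lowest fold changes among single-gene probe sets past the threshold whose groups did not overlap, or all of them if fewer. Where none passed, it took the 5 highest and 5 lowest as values that did not pass. In the other comparisons it took 5 in each direction. It also took up to 4 members of each list past the threshold, and the nicotianamine synthases. Probe sets annotated to several genes are not named. Any other gene or probe set is introduced as chosen after its values were seen.

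Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, using for each gene the probe set with the highest mean, and again with an estimated correlation. Of 25 lists fixed in advance, 12 had no named member on the array and 10 had 1 or 2, so that 3 with at least 3 members were tested: iron uptake (FIT-dependent), iron deficiency regulators (FIT-independent) and photosynthesis genes as markers of shoot tissue. The fixed lists held 273 genes, of which 24 had a named probe set. More families had been fixed in advance, with a minimum of 10 measured members. The 4 tested as such, named by symbol, were UDP-glycosyltransferases, cytochromes P450, glutathione S-transferases and expansins. A further 25 lists were drawn up after the annotation had been seen, with a minimum of 3 members. They took in some families planned beforehand, among them xyloglucan endotransglucosylases (9 members, below the planned minimum), defensins (13 members), tubulins and WRKY factors. The 3 kinds of list were adjusted separately, over 21, 28 and 175 tests.

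The procedure was tested on simulated data with 200 changed probe sets among 22746 at each size. At a log2 change of 0.5, 1 and 2 it recovered 47.5%, 96% and 99.5% for RNAi against WT in control medium, and 35.5%, 96.5% and 99% for added zinc against control in WT. Over both media it recovered 86.5%, 99% and 100% for the line effect, and over both lines 78%, 99% and 100% for the zinc effect. Between 0 and 17 unchanged probe sets were called beside these. The simulated noise was drawn independently for each probe set and array, so variation shared between genes was not represented.

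The alternatives tried were the replicate number as a block, median centring, a further quantile normalization, leaving out probe sets below the 40th percentile of mean signal, a trended and robust variance, array weights, a minimum log2 fold change of 1, only the 6 arrays compared, another probe set per gene, and leaving out each array in turn. Added after the data were seen were a replicate block within control medium only, leaving out the 2 arrays of lowest weight and taking the hybridization spike-in level as a covariate. For chance, the arrays were regrouped in all 10 splits of 6 arrays or in 100 drawn regroupings of 12, with seed 1. Control probe sets, used only for quality checks, were compared by exact permutation tests. Figures were drawn with matplotlib 3.10.9.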

Results

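Transcript levels were measured in roots of Arabidopsis halleri, which accumulates zinc in its leaves, in WT plants and in an RNAi line with suppressed AhNAS2. Nicotianamine synthases such as NAS2 make nicotianamine, a chelator of zinc, iron and copper in plants. The lines were grown in control solution or with 10 µM zinc added, with 3 arrays per group and 3 pooled plants per array. The level of the targeted gene and of the other nicotianamine synthases could not be read by name, because no probe set carried their names in the annotation used. Any probe set for them would be among the 8730 unnamed ones, which were tested without a name. The labels of the RNAi arrays were therefore not checked against their target.

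The comparison of RNAi and WT roots in control medium asked which transcripts differed with suppression of AhNAS2 without added zinc. AT4G18593, annotated as a relative of dual-specificity phosphatases, rose 7.29-fold in the RNAi line, from 5.71 ± 0.13 in WT to 8.57 ± 0.28 (log2 signal, SD, n = 3). Its log2 fold change was 2.87 (SE 0.17, limma adjusted p = 2.51e-05). AT5G49560 was 1.71-fold lower, at 7.03 ± 0.09 in WT and 6.26 ± 0.13 in RNAi, and fell by 0.77 on the log2 scale (SE 0.097, adjusted p = 0.0244). Of all probe sets tested 5 passed the threshold, 2 higher and 3 lower in RNAi, and the others were 1 probe set annotated to several genes, which fell by 2.97 (adjusted p = 0.0107), and 2 unnamed ones chosen after their values were seen. One of the unnamed rose by 0.93 (SE 0.12, adjusted p = 0.0281) and the other fell by 0.93 (SE 0.11, adjusted p = 0.0152). At an unadjusted p under 0.05 there were 1993 probe sets, against 1137 that chance would give on average. Probe sets vary together, so a chance count can lie well away from that mean, and its spread was not measured. The excess alone is therefore no sign of an effect. With the replicate number as a block over all 12 arrays 3 probe sets passed, and AT5G49560 and the 2 unnamed ones did not (adjusted p = 0.0513 each); with the block within control medium only 12 passed, these 3 among them (AT5G49560 adjusted p = 0.0454). The count was 1 without RNAi control replicate 1 or 2 and 20 without WT control replicate 2, and the call of AT4G18593 held in all 22 alternative settings and that of AT5G49560 in 12 of 22.

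With zinc added, AT4G18593 was again higher in RNAi, 5.75-fold (log2 fold change 2.52, SE 0.17, adjusted p = 0.000106), at 5.78 ± 0.25 in WT and 8.30 ± 0.24 in RNAi (SD, n = 3). AT1G71695, a class III peroxidase, rose 3.06-fold, from 4.34 ± 0.11 to 5.96 ± 0.16 (SE of the log2 fold change 0.19, adjusted p = 0.00752). AT3G44280 rose 1.79-fold (SE 0.11, adjusted p = 0.0238) and AT5G02240, a protein with a Rossmann fold, 1.69-fold (SE 0.097, adjusted p = 0.0168). AT1G12010, an ACC oxidase of ethylene synthesis, was 4.99-fold lower in RNAi, at 9.47 ± 0.08 in WT and 7.15 ± 0.37 in RNAi (SE 0.27, adjusted p = 0.00752). AT1G48750, of the lipid-transfer protein family, was 5.83-fold lower, at 9.74 ± 0.86 and 7.20 ± 0.36 (SE 0.35, adjusted p = 0.0261). In all, 12 probe sets passed, 5 higher and 7 lower, with 6 annotated to 1 gene, 2 to several and 4 unnamed; unadjusted p-values under 0.05 numbered 1756. Of the unnamed, chosen after their values were seen, 1 fell by 2.93 (SE 0.31, adjusted p = 0.00567) and another by 2.02 (SE 0.17, adjusted p = 0.000878), while 1 more rose by 0.83 (adjusted p = 0.0466). The count was 2 without WT zinc replicate 1, 4 without RNAi zinc replicate 2 and 29 without WT zinc replicate 3, and of 21 alternative settings the calls of AT1G48750 and of the unnamed probe set that rose held in 10, AT3G44280 in 13, AT5G02240 in 17, AT1G71695 and AT1G12010 in 19 and AT4G18593 in 21.

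**Figure D1:**
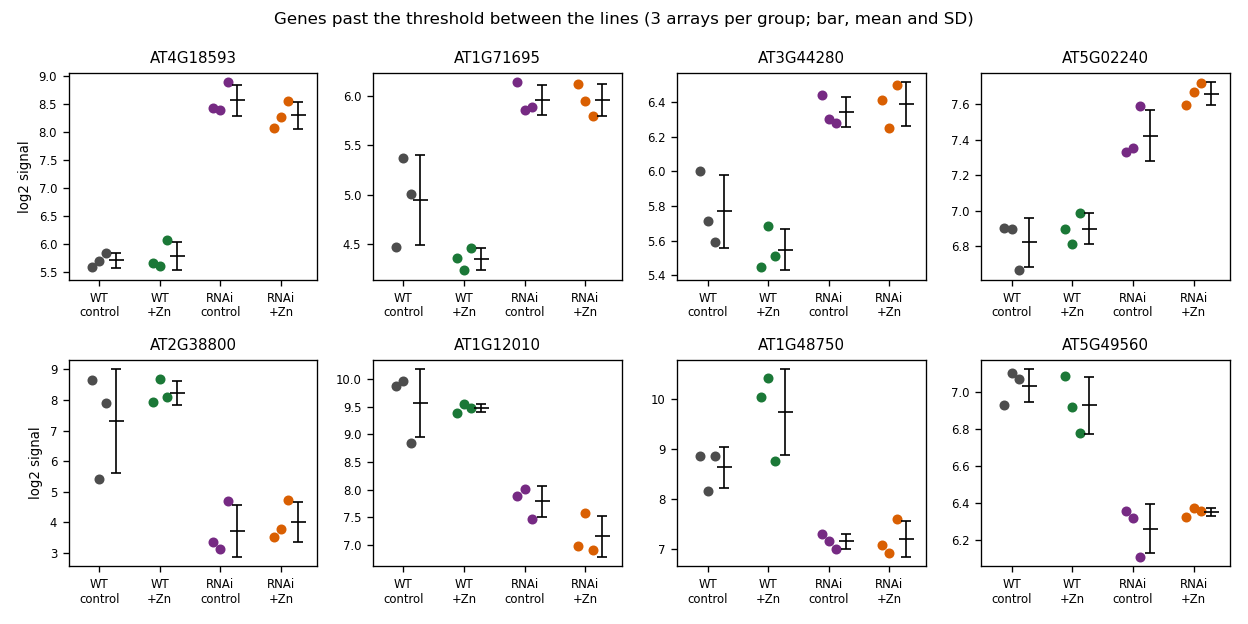
Log2 signal (vertical axis) of 8 genes past the threshold in at least 1 line comparison, by group (horizontal axis). Points are the 3 arrays of a group and bars the mean and SD; AT4G18593 lies near 5.7 in both WT groups and above 8 in both RNAi groups.

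Averaged over both media, the line effect was measured on 6 arrays per line. Genes that rose in RNAi were led by AT4G18593 (6.47-fold, adjusted p = 9.56e-07), the peroxidase AT1G71695 (2.49-fold, SE of the log2 fold change 0.13, adjusted p = 0.00137), AT5G43930 (1.98-fold, adjusted p = 0.00561), AT1G24575 (1.88-fold, adjusted p = 0.00393) and AT1G30130 (1.64-fold, adjusted p = 0.0345). Those that fell were led by AT2G38800, annotated as related to calmodulin-binding proteins, which fell by 3.91 on the log2 scale (SE 0.49, adjusted p = 0.00434). Its signal was 7.32 ± 1.70 and 8.24 ± 0.40 in WT and 3.73 ± 0.86 and 4.02 ± 0.64 in RNAi (control and zinc, SD, n = 3). The RNAi values lay below the array medians of 5.34 to 5.38, toward the lowest value of 2.46. Signal over background was not analysed, so the size of this fall is less certain than its direction. The ACC oxidase AT1G12010 was 4.13-fold lower (SE 0.19, adjusted p = 0.000872), the lipid-transfer protein AT1G48750 4.03-fold lower (adjusted p = 0.00434), AT5G01740 3.26-fold lower (adjusted p = 0.0282) and AT1G56610 3.23-fold lower (adjusted p = 0.0240). The calls of AT1G30130, AT5G01740 and AT1G56610 held in 10, 13 and 14 of 20 alternative settings, and those of the other 7 genes in all 20.

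In total 239 probe sets passed over both media, 91 higher and 148 lower in RNAi, of which 130 carried 1 gene, 7 several genes and 102 none. Only 20 of them changed by at least 1 on the log2 scale, 4 higher and 16 lower. Unadjusted p-values under 0.05 numbered 3016, against 1137 on average by chance, with the spread of a chance count not measured. Leaving out single arrays gave counts from 68, without RNAi control replicate 2, to 267, without WT control replicate 1. The 6-array counts are larger than those within a medium, where fewer arrays enter each mean, and do not show an effect of the medium.

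Further genes past the threshold over both media were chosen after their values were seen, and a shared function among them was not tested. AT1G14810, aspartate-semialdehyde dehydrogenase of the methionine, lysine and threonine pathway, fell by 1.22 (SE 0.18, adjusted p = 0.0128), with 6.60 ± 0.33 in WT and 4.96 ± 0.35 in RNAi in control medium. The DnaJ-type chaperone AT2G21510 fell by 1.37 (SE 0.21), the acidic ribosomal protein AT2G40010 by 0.95 (SE 0.14), AT5G47250 of the NB-LRR immune receptor family by 0.93 (SE 0.12) and the cathepsin B-like protease AT1G02300 by 0.89 (SE 0.17, adjusted p = 0.0355). AT2G26240 fell by 1.53, AT5G12350 by 1.06 and PRA1.B4, of a family of prenylated Rab acceptors, by 0.75. Those that rose changed less. CCOAMT, related to the caffeoyl-CoA O-methyltransferases of lignin synthesis, rose by 0.67 (SE 0.082, adjusted p = 0.00434), the major latex protein-like AT5G28010 by 0.58 (SE 0.10, adjusted p = 0.0261) and the actin-binding LIM protein WLIM1 by 0.47 (SE 0.070). The calls of AT1G02300 and AT5G28010 held in 9 and 12 of 20 alternative settings.

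Few members of the gene lists passed in this comparison. The cytokinin N-glucosyltransferase UGT76C2 fell by 0.39 (SE 0.082, adjusted p = 0.0469), the only 1 of 47 UDP-glycosyltransferases that passed over all genes, and adjusted over the list alone 2 passed. The defensin-like LCR68 fell by 0.30 (adjusted p = 0.0496), the jacalin lectin JAL33 by 0.62 (adjusted p = 0.0476) and TBL38, of a family of wall acetyltransferases, by 0.49 (adjusted p = 0.0290). The calls of UGT76C2, LCR68, JAL33 and TBL38 held in 4, 2, 8 and 10 of 20 alternative settings.

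The line effect in the media was compared across genes, which are not independent replicates, on separate arrays. The log2 fold changes of all probe sets correlated with r = 0.566, and 63.0% had the same sign. Among the other drawn regroupings of the arrays the highest r was 0.526. Of the 15 probe sets past the threshold in at least 1 medium, 15 had the same sign in both. AT4G18593 passed in both, as did the probe set annotated to several genes that fell in control medium, making 1 shared call in each direction where independent lists of these sizes would share 0.00044 and 0.00092. All 239 probe sets past the threshold over both media had the same sign in each medium, which their selection on the mean favours.

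**Figure D2:**
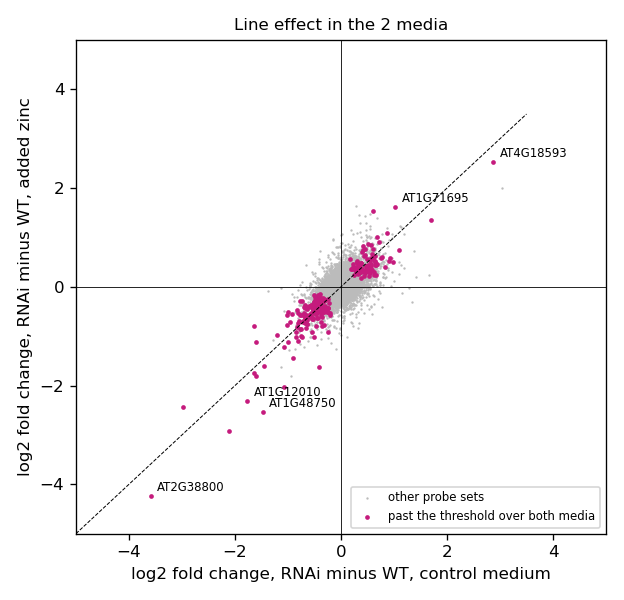
Log2 fold change of RNAi minus WT in control medium (horizontal axis) and in added zinc (vertical axis), 1 point per probe set. Coloured points are the 239 past the threshold over both media and the dashed line marks equal change; r across all probe sets was 0.566.

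Added zinc was compared with control medium to ask how roots of each line responded to the metal. In WT the highest named values were AT1G60590 (log2 fold change 1.13, SE 0.38), AT1G48750 (1.11, SE 0.35), AT5G11020 (0.94), AT4G22212 (0.94) and AT2G38800 (0.92, SE 0.69). The lowest were AT5G43590 (-1.46, SE 0.43), AT4G33730 (-1.08), petG of the chloroplast cytochrome complex (-1.03), the phosphoethanolamine methyltransferase AT1G73600 (-1.02) and AT5G06630 (-0.91). Each of these 10 had an adjusted p of at least 0.97, and single WT control arrays moved AT2G38800 between -0.036 and 1.58 and AT4G22212 between 0.13 and 2.24. No probe set passed limma's threshold (0 of all tested), with 1147 at an unadjusted p under 0.05 against 1137 by chance, and the smallest adjusted p was 0.428.

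In RNAi roots the highest values with zinc were the nitrate transporter NRT2.5 (0.97, SE 0.57), AT1G60590 (0.76, SE 0.38), AT1G80320 (0.71), AT1G64560 (0.70) and AT2G43390 (0.68). The lowest were AT1G20380, of the prolyl oligopeptidase family (-1.33, SE 0.26), the linker histone HIS1-3 (-1.18, SE 0.83), AT1G14960 (-1.16), the peroxidase AT4G33420 (-1.03, SE 0.26) and AT1G12030 (-0.90, SE 0.20). Over the alternative settings NRT2.5 ran from 0.33 to 2.32, AT2G43390 from 0.21 to 1.36 and HIS1-3 from -1.70 to 1.395. Again 0 probe sets passed with limma, 1027 had an unadjusted p under 0.05 and the smallest adjusted p was 0.896.

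Over both lines the highest values were AT1G60590 (0.94, SE 0.27), AT1G64560 (0.69), AT5G11020 (0.67), the methionine gamma-lyase MGL (0.63, SE 0.19) and the mitochondrial nad2 (0.63, SE 0.14), and the lowest AT1G73600 (-0.94, SE 0.29), AT1G14960 (-0.92), AT4G33730 (-0.92), AT5G43590 (-0.90) and AT1G20380 (-0.89, SE 0.18). With limma 0 probe sets passed, and the smallest adjusted p was 0.225. An unadjusted p under 0.05 was found for 1734, against 1137 on average by chance, with the spread of a chance count not measured. The count was 2 with the replicate block and 0 to 4 with single arrays left out. The zinc effects of the lines correlated across genes with r = 0.293, and 58.4% of probe sets had the same sign. In simulated data a log2 change of 0.5 was recovered in 35.5% of cases for zinc in WT and in 78% over both lines, so many zinc effects of that size or smaller would have been missed. Noise shared between genes was not simulated, so these shares need not hold for the real arrays and larger zinc effects are not excluded. Hybridization spike-in controls, which carry no plant RNA, were lower on the zinc arrays in both lines, with a mean difference of -0.32 (exact permutation p = 0.00217, two-sided; adjusted p = 0.0260 over 12 control tests). With that level as a covariate the values of petG in WT, HIS1-3 in RNAi, and AT1G14960 and AT1G60590 in RNAi and over both lines changed sign, and AT1G60590 in WT was at 0.077. Because the spike-in level parts the media in both lines, the covariate and zinc overlap. The sign changes therefore cannot show which of them moved these values.

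No gene showed a line-dependent zinc effect past the threshold: 0 probe sets passed with limma and the smallest adjusted p was 0.9999. An unadjusted p under 0.05 was found for 497, fewer than the 1137 that chance would give on average. The highest interaction values were the calmodulin-like CML37 (1.35, SE 0.76), AT5G04120 (1.29, SE 0.70), AT5G43590 (1.13), AT1G80320 (1.05, SE 0.36) and AT3G29970 (0.96). Over the alternative settings CML37 ran from 0.82 to 1.96, AT5G43590 from 0.63 to 1.73 and AT3G29970 from 0.46 to 1.65. The lowest interaction values were AT3G12900 (-1.17, SE 0.49, from -1.45 to -0.68 over these settings), AT1G48750 (-1.06, SE 0.50), AT4G22212 (-1.03, SE 1.16, from -2.33 to -0.22 over left-out arrays), AT1G80380 (-0.98) and AT4G38810 (-0.96). The genes that passed between the lines in 1 medium alone are therefore not shown to differ between media.

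Of the 3 fixed lists tested, iron uptake had the clearest shift, with 4 of its 17 genes measured. FIT, IRT1 and FRO2 were among those without a named probe set. With zinc added, all 4 members with a named probe set were lower in RNAi than in WT, with a median log2 fold change of -0.42 (camera adjusted p = 0.0146, but adjusted p = 0.462 with an estimated correlation). None passed over all genes and 2 passed adjusted over the list alone. AT3G12900, the scopoletin hydroxylase of coumarin synthesis, was at 9.17 ± 0.36 in WT and 7.90 ± 0.31 in RNAi (-1.27, SE 0.35, adjusted p = 0.344). AT3G13610, the feruloyl-CoA hydroxylase of the same pathway, was at 10.5 ± 0.41 and 9.81 ± 0.23 (-0.68, SE 0.19, adjusted p = 0.361). The glucosidase BGLU42 (-0.17) and the metal carrier AT3G58060 (-0.13) lay closer to 0. Over both media the median was -0.30 (adjusted p = 0.0314, and adjusted p = 0.462 with an estimated correlation), and in control medium -0.15 (adjusted p = 0.420). The interaction of line and zinc did not pass for this list (median -0.36, adjusted p = 0.201). Of 100 regroupings of the arrays, 35 gave at least the 2 fixed-list calls found here, so chance cannot be excluded for either call. The call in added zinc ended without WT zinc replicate 2 or RNAi zinc replicate 3, and that over both media without any of WT control replicate 3, WT zinc replicate 2, RNAi control replicate 1 and RNAi zinc replicates 2 and 3.

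Regulators of the iron deficiency response that act beside FIT did not pass. The 3 with a named probe set were BHLH101 (-0.54, SE 0.26, RNAi against WT with zinc), PYE (-0.062, SE 0.089) and AT1G47400, a small iron-regulated peptide (-0.029, SE 0.49), with a list median of -0.062 (adjusted p = 0.420) and of 0.043 over both media (adjusted p = 0.945). AT1G47400 varied within groups, with an SD of 1.25 in WT control. BHLH101 and PYE had group means of 4.41 to 4.95, below the array medians of 5.34 to 5.38, where a difference may go unseen.

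Of the zinc deficiency response only ZIP9, a zinc transporter gene that zinc deficiency induces, had a named probe set, and the other members were not analysed here. ZIP9 was at 10.8 ± 0.40 in WT control, 9.92 ± 0.29 in WT zinc, 10.6 ± 0.81 in RNAi control and 10.0 ± 0.57 in RNAi zinc. The zinc effect over both lines was -0.72 (SE 0.27, adjusted p = 0.581), with -0.84 (SE 0.38) in WT and -0.61 (SE 0.38) in RNAi. ZIP9 was also among the genes that followed the largest axis of variation between replicates most strongly (slope -1.34), as was the root hair expansin EXPA18 (-1.28). Its level differed between the lines by -0.021 (SE 0.27, adjusted p = 0.986). The zinc-sensing factor bZIP19 (0.014, SE 0.089), the transporter ZIP6 (-0.10, SE 0.097) and the manganese carrier MTP11 (0.073, SE 0.091) showed smaller zinc effects over both lines, none past the threshold.

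**Figure D3:**
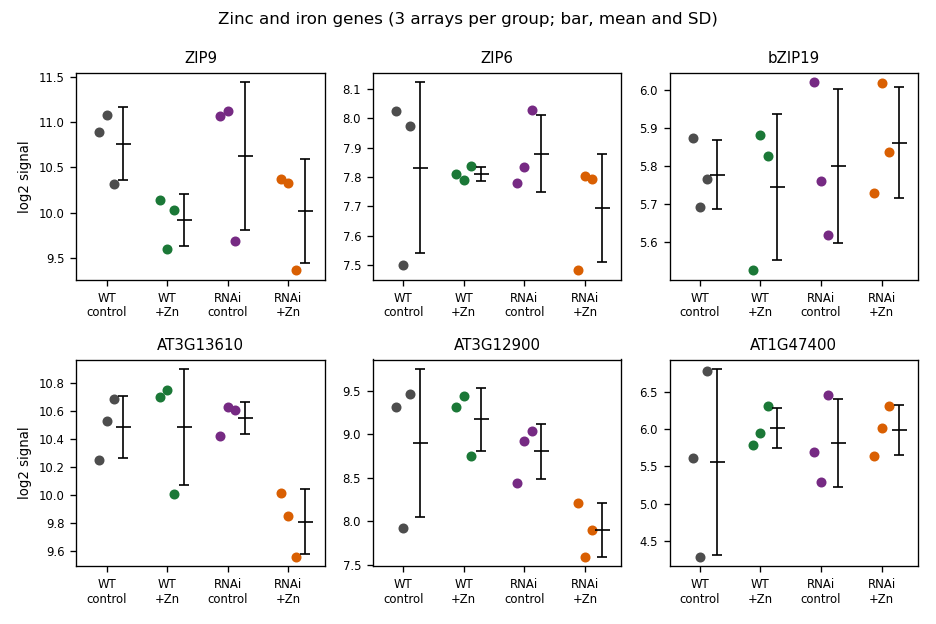
Log2 signal (vertical axis) of 6 zinc and iron genes by group (horizontal axis), with the 3 arrays of a group as points and bars for the mean and SD. AT3G12900 and AT3G13610 were lowest in RNAi roots with zinc, at 7.90 and 9.81, but no gene shown passed the threshold.

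Of the other fixed lists 12 had no named probe set and were not analysed here, and no named gene of the rest passed. The copper chaperone CCS was at 6.22 ± 0.29 in WT and 6.92 ± 0.26 in RNAi in control medium (0.70, SE 0.19, adjusted p = 0.249) and differed by 0.49 over both media (adjusted p = 0.117). Over both media the line differences of the stress genes were -0.061 for the small heat shock gene AT1G53540, -0.060 for AT2G21640 and 0.0093 for GSTU25, of the defensin PDF1.2 -0.0019, and of the flavonoid enzyme DFR 0.095. AT2G21640, GSTU25, PDF1.2 and DFR had group means of 3.45 to 4.3, below the array medians of 5.34 to 5.38. Signal over background was not analysed, so their small differences do not show that these genes were unchanged. The root hair expansins EXPA7 and EXPA18 were at -0.48 (SE 0.22, adjusted p = 0.656) and -0.46 (SE 0.25, adjusted p = 0.714) with zinc over both lines, and the clock gene GI at 0.28 (SE 0.13, adjusted p = 0.655). Photosynthesis genes, as markers of shoot tissue, had a median line difference of -0.022 over both media (4 members, camera adjusted p = 0.992) and a median zinc difference of -0.082 over both lines (adjusted p = 0.527). Of these, RCA, SBPASE and PRK also lay below the array medians in every group, where a difference may go unseen.

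None of the 4 gene families passed in any of 28 tests. Over both media the median line difference was -0.0059 for 47 UDP-glycosyltransferases (adjusted p = 0.994), -0.021 for 26 cytochromes P450 (adjusted p = 0.794), 0.031 for 14 glutathione S-transferases (adjusted p = 0.685) and -0.027 for 18 expansins (adjusted p = 0.987).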

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

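The tests of array processing and of the amount of labelled RNA were chosen after the spike-in result was seen, and the reading of the second was rewritten after its value was known; the counts over regrouped arrays were fixed beforehand.

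Hybridization spike-ins (bioB, bioC, bioD and cre, 18 probe sets), which the comparisons between plants do not use, stood out because they differed between the media. Their mean was 10.2 ± 0.03 in WT control, 9.95 ± 0.12 in WT zinc, 10.3 ± 0.16 in RNAi control and 9.90 ± 0.06 in RNAi zinc (log2 signal, SD, n = 3), a zinc minus control difference of -0.3238 (exact permutation p = 0.00217, adjusted p = 0.0260 over 12 tests, lower in 6 of 6 zinc arrays than in any control array of the same line). It was -0.32 after median centring and -0.30 after a further quantile normalization, but these settings changed little else and so do not test array scaling, which stays open. Array processing that differed between the media may account for it: 0 zinc arrays lay at or above a control array of their line, but no label gives a batch and medium and batch cannot be told apart. Different amounts of labelled plant RNA could also matter: the Bacillus spike-ins shifted by 0.17 (SE 0.11), 0.4971 (SE 0.072) more than the hybridization spike-ins, yet the labels do not state when either control was added, so this stays open, as does an effect of zinc on the plant RNA itself, which was not tested.

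GAPDH control probe sets differed between RNAi and WT by -0.25 (exact permutation p = 0.00866, adjusted p = 0.0520 over 12 tests), and actin ones by -0.097 (p = 0.0390 by the same permutation test, adjusted p = 0.156), and neither passed.

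Regrouped arrays were used to ask whether chance could give such counts. For RNAi against WT over both media, 1 of 100 regroupings, the real one, gave 239 calls or more, and the highest other gave 42. Chance is thus an unlikely source of that count, though 1 of 100 is the smallest share these draws allow. The correlation of 0.566 between the line effects was also reached by 1 of 100, but the highest other was close to it at 0.526. With single arrays left out the real r was 0.478 to 0.565. The correlation thus stands less clearly apart from the regroupings than the count does. For the zinc effects 8 of 100 reached the real r of 0.293, up to 0.432, so chance cannot be excluded there. For RNAi against WT in control medium (5 calls, highest other 0, reached by 1 of 10) and in added zinc (12 calls, highest other 0, 1 of 10) the splits are too few for a share under 0.05. In control medium, where the numbers may pair the arrays, the 3 other splits that also part all 3 pairs gave 0 calls. So did the 6 that part 1 pair. A count of 0 is reached by every split, so splits say nothing about chance for added zinc in WT (10 of 10, highest other 1), added zinc in RNAi (10 of 10, highest other 0), zinc over both lines (100 of 100, highest other 1), the interaction (100 of 100, highest other 1) and the gene families (100 of 100, highest other 5). Among the gene lists, 35 of 100 regroupings gave at least the 2 calls of the fixed lists, with up to 10, and 88 of 100 gave the 6 calls of the added lists, with up to 30. Chance can therefore not be excluded for any list call, those of iron uptake included. Some regroupings gave several times the real number, and whether structure among the arrays or too low a preset correlation between genes produced this was not tested.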

How the results depend on the processing

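Leaving out the 2 arrays of lowest weight (WT control replicate 2 and RNAi zinc replicate 1), the spike-in covariate, the replicate block within control medium only, and all alternatives of the added lists and of the zinc correlation were chosen after the data were seen. The counts for added zinc in WT, added zinc in RNAi and the interaction stayed at 0 in every setting except 1 probe set in WT without WT control replicate 1.

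RNAi against WT in control medium (5 calls) gave 3 with the replicate block (2 shared), 12 with the replicate block within control medium only (5 shared), 9 without dim probe sets, 11 with trend and robust variance, 31 with array weights, 2 at a log2 fold change of at least 1, 17 without the 2 arrays of lowest weight, 3 with the spike-in covariate and 3 with only the 6 arrays compared. Left-out arrays gave 1 to 20: 14, 20 and 15 without WT control replicates 1, 2 and 3, 11 and 17 without WT zinc replicates 2 and 3, 1, 1 and 3 without RNAi control replicates 1, 2 and 3, and 3 without RNAi zinc replicate 2 or 3. In added zinc (12 calls) the other settings gave 9 to 18, and left-out arrays 2 to 29: 22 and 25 without WT control replicates 1 and 2, 2 and 29 without WT zinc replicates 1 and 3, 7 without RNAi control replicate 2, and 4 and 6 without RNAi zinc replicates 2 and 3. RNAi versus WT over both media (239 calls) had 20 left at a log2 fold change of at least 1. For it the replicate block gave 165 (149 shared), array weights 347 (237 shared), the covariate 168 (159 shared) and the 2 omitted arrays 167 (122 shared). Left-out arrays gave 68 to 267: 82 and 138 without WT zinc replicates 1 and 2, 85, 68 and 130 without RNAi control replicates 1, 2 and 3, and 91 and 92 without RNAi zinc replicates 2 and 3. Zinc over both lines (0 calls) gave 2 with the replicate block and 0 to 4 with left-out arrays, 1 without WT zinc replicate 3 and 4 without RNAi control replicate 3. The cause of these shifts was not tested.

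The line correlation was 0.478 to 0.565 and the zinc correlation 0.221 to 0.294 over left-out arrays. The 2 calls of the fixed lists fell to 0 with an estimated correlation and were 0 to 4 over left-out arrays (0 without WT zinc replicate 2 or RNAi zinc replicate 3, 1 without RNAi zinc replicate 2, 4 without WT zinc replicate 3). The 6 of the added lists fell to 0 with an estimated correlation and to 0 without dim probe sets, and were 1 to 10 over left-out arrays (1 without WT control replicate 1, 10 without WT control replicate 3, 3 without WT zinc replicate 1, 2 without RNAi zinc replicate 3).

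AT4G18593 kept its direction and call in every setting of each line comparison. Among zinc effects that had not passed, AT2G38800 in WT reversed to -0.036 without WT control replicate 2 and without the 2 arrays of lowest weight (range -0.036 to 1.58). With the spike-in covariate petG in WT reversed to 0.25, AT1G60590 to -0.66 in RNAi and -0.29 over both lines, AT1G14960 to 0.091 in RNAi and 0.16 over both lines, and HIS1-3 in RNAi to 1.395. The cause was not tested.

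Over all groups the replicate numbers did not clearly pair the samples: 8 of 18 same-numbered pairs correlated above 0.1 (from -0.45 to 0.48) and 5 of 12 arrays correlated best with their own number. These few arrays can neither show nor exclude pairing, so the choice between a model with and without the block stays open. In control medium all 3 pairs of WT and RNAi arrays correlated above 0.1 (0.16 to 0.48), and 1 of 6 ways to match them, the labelled one, had so high a mean, a hint from the data and not the design. Camera takes no robust variance, so the lists were run with a trend only, and alternatives for the NAS2 level were not run because no probe set carried its name. Signal over background was not analysed here, since the deposited summaries give none.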

Other observations

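The 25 lists drawn up after the annotation had been seen, the test of shoot tissue and the test of locus order were chosen after the data were seen; the tests of RNA degradation and of array signal against the largest axis were fixed before their values were computed.

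Xyloglucan endotransglucosylases and chloroplast-encoded genes gave the only list calls outside iron uptake, all downward. The former had been planned as a family, fell short of its minimum of 10 members and entered with the lists drawn up later. The 9 xyloglucan endotransglucosylases, which remodel wall xyloglucan, had a median line difference of -0.34 with zinc (adjusted p = 0.0362) and -0.24 over both media (adjusted p = 0.0113), both at adjusted p = 0.995 with an estimated correlation. Over both media 8 of 9 were negative, 0 passed over all genes and 3 passed adjusted over the list alone, among them XTH19 (-0.32, SE 0.069, adjusted p over all genes 0.0519) and XTH18 (-0.36, SE 0.097, adjusted p 0.117). Both calls also ended without dim probe sets, without WT zinc replicate 1 and without RNAi zinc replicate 3, and that with zinc without WT control replicate 1 (medians from -0.42 to -0.12 with zinc and -0.35 to -0.13 over both media). The 69 chloroplast-encoded genes had median differences of -0.15 for RNAi against WT in control medium (adjusted p = 0.00377), -0.092 over both media (adjusted p = 0.00377), -0.091 for zinc in WT (adjusted p = 0.00549) and -0.088 for zinc over both lines (adjusted p = 0.00549), each at adjusted p = 0.995 with an estimated correlation and with 0 members past the threshold. All 4 calls ended without dim probe sets and without WT control replicate 1, the line calls also without RNAi control replicate 2 or 3 (control medium) and WT zinc replicate 2 or RNAi zinc replicate 3 (both media). Those for zinc ended without WT zinc replicate 1 or 3 and, over both lines, without RNAi control replicate 1 or RNAi zinc replicate 3 (medians from -0.20 to -0.037 in WT and -0.15 to -0.042 over both lines). For 24 nuclear photosynthesis genes the median over both media was -0.018 (adjusted p = 0.964), for 16 mitochondrion-encoded genes 0.038 (adjusted p = 0.566), for 13 defensins -0.064 (adjusted p = 0.136), for 16 genes of glucosinolate synthesis and ER bodies -0.034 (adjusted p = 0.344) and for 22 TBL acetyltransferases 0.022 (adjusted p = 0.717), while camera ranked the last of these downward.

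The axis of largest variation among replicates, after the group means were removed, held 33.6% of the residual variance and the next 21.3%. FIT-independent iron regulators had the highest median slope along it (0.87, 3 of 3 positive), then mitochondrion-encoded genes (0.45, 12 of 16), and xyloglucan endotransglucosylases (-0.41, 8 of 9 negative), tubulins (-0.33, 7 of 7) and serine carboxypeptidase-like genes (-0.26, 27 of 29) the lowest. The spike-in level followed the axis with r = 0.2209 (SE 0.34, exact permutation p = 0.524, rho = 0.24, p = 0.522, adjusted p = 0.524 and 0.522). It was r = 0.28 without the 2 farthest arrays (12 arrays, 1296 within-group orders, 3 relations tested). By the rule fixed beforehand this argues against array signal as the source of the axis. With so wide an SE, however, a stronger relation is not excluded. RNA degradation, read from the 3' minus 5' signal of the control genes, may contribute: r = 0.5077 (exact permutation p = 0.148, rho = 0.45, p = 0.194; adjusted p = 0.222 and 0.292), which fell to 0.31 without the 2 farthest arrays. Shoot tissue in the roots could also contribute, since nuclear photosynthesis genes followed the axis with r = -0.6823 (exact permutation p = 0.0656, rho = -0.63, p = 0.0471; adjusted p = 0.197 and 0.141; r = -0.41 without the 2 farthest arrays), although their mean moved only between 4.61 and 4.83, below the array medians, the highest, LIL3:1, was at 6.20 in WT control, and the 69 chloroplast-encoded genes, which shoot tissue also carries, had a median slope of 0.047 (39 positive, 30 negative); both stay open, as does growth state, which no label gives.

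Linked sequence differences between the genotypes are a candidate explanation for line differences shared by both media, because probes of 1 species read another. If they were the cause, the 112 genes past the threshold with a locus code should lie closer in locus order, among 11798 loci, than random genes. This holds only where the order of the A. thaliana locus codes matches gene order in A. halleri, which was not examined. Pairs of loci that lie next to each other, or nearly so, were left out of all counts below. Clustering at the shortest distances was therefore not tested. Pairs within 20, 50 and 100 loci numbered 17, 54 and 117, against 15.5, 46.8 and 98.1 in random draws (permutation p = 0.375, 0.173 and 0.0370; smallest adjusted p for this comparison 0.2142 over the 21 tests of the 7 comparisons). Within 100 loci the 112 top genes gave 121 pairs for RNAi against WT in control medium (permutation p = 0.01, adjusted p = 0.210, the smallest of the 21), 111 in added zinc (p = 0.1), 104 for the interaction (p = 0.262), and for zinc 115 in WT (p = 0.0440), 89 in RNAi (p = 0.830) and 109 over both lines (p = 0.146). None passed after adjustment, so sequence differences and suppression of AhNAS2 cannot be told apart for these genes.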
